A study of Mus musculus with 6 samples.

How the data were processed

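The data were RNA-seq of polyadenylated RNA from mouse embryonic stem cells, in 6 libraries that the labels put in 2 groups of 3, wild-type Nanog (WT) and Nanog R153A. Per the labels, the cells were grown on gelatin-coated dishes in medium with serum and LIF under normal culture, and how R153A was introduced and whether the libraries of a group came from separate cultures or clones are not given in the sources used here. The authors deposited 1 table of FPKM values with 1 value per gene symbol and library, 24083 symbols in all. Per the submitters' processing notes, Bowtie2 2.3.4.3, SAMtools 1.9, HTSeq 0.11.2, edgeR 3.26.8 and the mouse build mm9 were used, with no role or order given. The tool that gave the FPKM values, the gene annotation, the use of strand and the filters are not given in the sources used here. The FPKM values were not whole multiples of a per-read step, so read counts and depth could not be recovered, no count test was run and no counting intervals are given. Hmgcs1, a gene of sterol synthesis that cells use in general, was listed at 0 in all 6 libraries, so a value of 0 can be a failed estimate and is reported only as listed at 0.

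The values were used as deposited, without further scaling, as log2(FPKM + 1). The pseudocount of 1 lowers the fold changes of genes near or under 1 FPKM. Genes with an FPKM of 1 or more in at least 3 of the 6 libraries were tested, which left 11817 genes. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend and moderated variances, 2-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and called with at least a 2-fold change where its log2 fold change was also 1 or more in size. For Nanog and Wdr5 an exact permutation test of the 2 groups was added. Ratios of mean FPKM are given as folds only where the gene reached 0.1 FPKM in every library. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

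The test, the filter, the gene lists, the rule for named genes and all alternatives but the GC and length correction were fixed before the data were examined. There were 28 gene lists with 651 entries, of which 647 were in the table. They covered core, naive and formative or primed pluripotency, primitive endoderm, mesoderm and primitive streak, neuroectoderm, trophectoderm, the two-cell-like state, WDR5 and COMPASS subunits, the LIF and STAT3 pathway, Nodal and BMP signalling, WNT targets, FGF and ERK response, DNA methylation machinery, Polycomb, Hox genes, germline genes, imprinted genes, fibroblast and feeder markers, p53 targets, integrated stress and heat shock response, glycolysis and hypoxia, cholesterol biosynthesis, cell cycle, cytosolic ribosomal proteins, interferon response, extracellular matrix and adhesion, and sex-linked dosage markers. Some genes stand in more than 1 list, such as Klf4, Tfcp2l1, Krt18, Cdx2, T, Wnt3, Etv4 and Ddit4. The 27 lists with at least 5 tested members were tested with camera, from limma, which compares a list with the other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Ranges of a list's adjusted p over the alternatives are those of camera at the preset correlation.

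The rule for named genes took Nanog and Wdr5, then the 10 largest rises and 10 largest falls among genes past the adjusted threshold with non-overlapping groups and a mean of at least 2 FPKM in the higher group. Symbols made of Gm and digits, ending in Rik or formed like clone codes were left out of that part. It then took up to 4 called members of each list by the size of the change, or the 2 with the highest mean FPKM where none was called. Some genes that this rule took are not reported here. Other members are named where a count was 5 or fewer, and these, as well as Gm5643, Mir675, Hmgcs1, Dnmt3b, Ddx3y, Eif2s3y and the gene families in the closing section, were chosen after their values were seen.

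The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a filter of 5 FPKM, median-ratio scaling, rescaling to TPM, quantile normalization, limma without a trend, robust moderation, the replicate number as a block, and leaving out each library in turn. A loess correction of each library on GC content and transcript length (span 0.5) was added after the data were seen. GC content and length came from GENCODE M21 transcripts and were matched by symbol for 11756 (99.5%) of the genes tested. That annotation is for another build than mm9, so no coordinates are given, and chromosomes were used only to group genes. The reading frame of Nanog was the longest one in the same transcripts. The 6 libraries were also refitted in all 10 splits into 3 and 3.

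The fit was tested on simulated data for the comparison of 3 R153A with 3 WT libraries, with 200 changed genes among 11817. It recovered 20% of the genes changed by 0.25 on the log2 scale, 84% of those changed by 0.5, 98% of those changed by 1 and 100% of those changed by 2. Of the unchanged genes 0.0259% were called, which made up 1.71% of the calls. Camera called the 1 list that had been shifted besides these genes, naive pluripotency, and no other. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.821, for the two-cell-like state. Far more genes were also called in the data (7062). The simulation therefore does not show how often camera calls lists wrongly in these data. Genes with near-identical copies or overlapping neighbours are uncertain because the rule for shared reads is not given in the sources used here. Among those named they are the ribosomal protein genes, the Xlr, H2 and gamma-protocadherin families, Zscan4c, Gm4340 and Gm5662, as well as H19 with Mir675 and Xist with Tsix. Nanog also has processed pseudogenes, whose reads cannot be set apart here.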

Results

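Polyadenylated RNA was sequenced from mouse embryonic stem cells, pluripotent cells of the early embryo kept here on gelatin in serum medium with LIF, the cytokine that sustains their self-renewal. There were 3 libraries from cells with wild-type Nanog (WT) and 3 libraries from cells with the R153A form of Nanog. Expression was given as FPKM (fragments per kilobase of gene model, scaled to the mapped fragments of a library) for 24083 genes per library. The FPKM values summed to between 360152 and 382086 per library, and the depth behind them was unknown because no read counts were given. In the WT libraries, 11147, 11221 and 11257 genes reached an FPKM of 1, compared with 11750, 11642 and 11759 in the R153A libraries. Across the 11817 genes tested, Pearson correlations of log2(FPKM + 1) lay between 0.995 and 0.996 within groups and between 0.947 and 0.950 between groups. Genes are not independent replicates in such a correlation. The first principal component held 89.7% of the variance and separated the WT from the R153A libraries, and the second held 3.07%. Values are mean ± SD over the 3 libraries of a group. Log2 fold changes are R153A minus WT of log2(FPKM + 1), a scale that understates changes of genes with low FPKM.

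The comparison addressed how expression differs between cells with wild-type and R153A Nanog. NANOG is a homeodomain transcription factor of pluripotent cells, and the series also concerns WDR5, a shared scaffold subunit of COMPASS histone methyltransferases. In the reference transcript Nanog-201, whose longest open reading frame encodes 305 residues, the residue that R153A names is arginine. Its codon is CGG at coding positions 457 to 459, counted from 1 at the start codon, within the peptide RMKCKRWQKNQ. Nanog mRNA fell from 253 ± 10.02 to 123 ± 5.16 FPKM, a 2.05-fold lower mean, with a log2 fold change of -1.03 (SE 0.0506, limma adjusted p = 2.5e-08). Wdr5 mRNA fell from 65.3 ± 1.63 to 42.0 ± 0.982 FPKM, a 1.56-fold lower mean, with a log2 fold change of -0.63 (SE 0.0460, limma adjusted p = 5.9e-07). For both genes the 3 R153A values lay below the 3 WT values, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow.

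Of the 11817 genes tested, 7062 (59.8%) differed between R153A and WT at a limma adjusted p under 0.05, of which 4428 were higher and 2634 lower in R153A. The higher genes made up 62.7% of these calls, but 50.7% under median-ratio scaling (3764 higher and 3655 lower). It was 47.4% under quantile normalization (3515 and 3893) and 49.7% after a GC and length correction (3776 and 3819). Rescaling to TPM left 58.9% of the calls higher (4197 and 2925), and 71.3% of those of at least 2-fold. At least 2-fold changes passed for 980 genes, 707 higher and 273 lower (72.1% higher), and under quantile normalization for 493 higher and 390 lower genes (55.8% higher). They passed for 1561 genes with a pseudocount of 0.1 and for 608 with a filter of 5 FPKM. The 3 R153A values lay wholly on one side of the 3 WT values in 65.0% of the genes tested, where chance gives 10%. The median absolute log2 fold change was 0.24, against a median residual SD of 0.083 between libraries of a group.

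The 10 largest rises among the genes eligible for naming were those of Pnmal1, Wnt8a, Gbp2, Apela, Pim2, Igfbp3, Sema6a, Krt8, Ltb and Sp5. Pnmal1 was listed at 0, 0.139 and 0.0770 FPKM in WT and at 20.6, 18.3 and 20.3 FPKM in R153A. Its log2 fold change was 4.27 (SE 0.0806, limma adjusted p = 4.6e-11). Wnt8a, a WNT ligand of the primitive streak, rose from 0.197 ± 0.0527 to 15.9 ± 1.74 FPKM (log2 fold change 3.81, SE 0.0893, limma adjusted p = 2.4e-10). Gbp2, an interferon-inducible GTPase, rose from 2.20 ± 0.246 to 42.8 ± 1.81 FPKM, and Apela, a peptide hormone of the apelin receptor, rose from 3.68 ± 0.295 to 53.8 ± 3.27 FPKM. The serine/threonine kinase gene Pim2 rose 11.8-fold, from 20.98 ± 1.53 to 247 ± 13.1 FPKM. Igfbp3, which encodes an IGF-binding protein, rose from 2.62 ± 0.178 to 37.9 ± 2.68 FPKM, and Sema6a, a semaphorin, from 0.791 ± 0.0380 to 16.1 ± 1.01 FPKM. Ltb, a lymphotoxin subunit of the TNF family, rose from 1.82 ± 0.269 to 23.3 ± 0.235 FPKM, and Sp5, a zinc-finger factor induced by WNT signalling, from 0.108 ± 0.0247 to 8.42 ± 0.568 FPKM. These 10 log2 fold changes had SEs between 0.0612 and 0.0893.

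The 10 largest falls were those of Tcl1, Klf4, Prdm14, Serpinb6c, Nr0b1, Crtac1, Sept1, Inhbb, Slc13a5 and Esrrb. Tcl1, Klf4, Prdm14, Nr0b1 and Esrrb belong to the naive pluripotency list. Tcl1, a coactivator of AKT kinases, fell from 53.7 ± 1.02 to 7.33 ± 0.804 FPKM, a log2 fold change of -2.72 (SE 0.0687, limma adjusted p = 3.2e-10). Klf4, a Krüppel-like factor used in reprogramming, fell from 55.9 ± 1.64 to 7.98 ± 0.121 FPKM, a 6.999-fold lower mean, with a log2 fold change of -2.66 (SE 0.0502, limma adjusted p = 4.6e-11). Serpinb6c, a serine protease inhibitor gene, fell from 11.9 ± 0.718 to 1.19 ± 0.113 FPKM, and Sept1, a septin GTPase gene, from 69.8 ± 4.32 to 13.1 ± 0.327 FPKM. Inhbb, which encodes the activin B subunit, fell from 5.37 ± 0.316 to 0.289 ± 0.0698 FPKM, and Slc13a5, a citrate transporter, from 4.76 ± 0.606 to 0.181 ± 0.00895 FPKM. Crtac1 fell from 9.04 ± 0.784 to 0.850 ± 0.222 FPKM. All 20 of these genes kept non-overlapping libraries between the groups, as the rule for naming required.

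**Figure D1:**
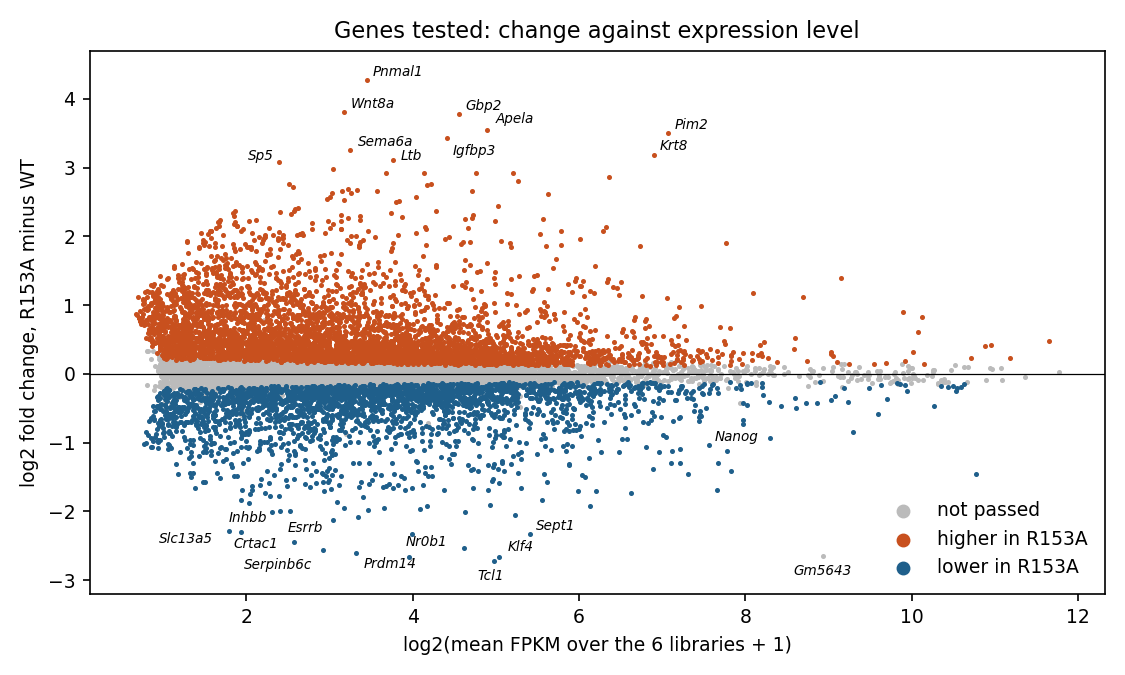
Each point is a gene tested, with log2 of its mean FPKM over the 6 libraries plus 1 on the x axis and its log2 fold change (R153A minus WT) on the y axis. Orange points are the 4428 genes higher in R153A, blue points the 2634 lower genes and gray points the genes not past a limma adjusted p of 0.05. Gm5643 was not past the test because its R153A libraries varied widely (402 ± 347 FPKM). The 20 genes with the largest changes eligible for naming and Nanog are labelled.

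Genes of naive pluripotency, the ground state of the preimplantation epiblast, fell almost throughout. Of 24 tested, 22 fell, 1 rose and 1 did not pass, and 23 fell and 1 rose when adjusted over the list alone. Prdm14, a repressor of differentiation genes, fell from 16.1 ± 0.602 to 1.81 ± 0.152 FPKM. Nr0b1, an orphan nuclear receptor, fell from 40.9 ± 1.08 to 6.24 ± 0.865 FPKM, and Esrrb, an orphan nuclear receptor that sustains self-renewal, from 12.5 ± 3.51 to 2.08 ± 0.728 FPKM. The only member that rose was Rex2 (17.7 ± 2.22 to 22.0 ± 2.66 FPKM), a call that ended in 5 alternatives, among them median-ratio scaling (limma adjusted p = 0.0602). Gbx2 stood at 3.04 ± 0.240 FPKM in WT and 2.58 ± 0.0801 in R153A. The list moved down (camera adjusted p = 1.8e-16). Its p ranged from 8.0e-20 to 2.8e-12 over the alternatives. It had an adjusted p = 0.215 with an estimated correlation. Of the 19 core pluripotency factors tested, 11 fell, 6 rose and 2 did not pass, with the same counts when adjusted over the list alone. Under median-ratio scaling 12 fell and 4 rose. Sox2, a partner of OCT4, fell from 209.8 ± 5.13 to 84.5 ± 3.86 FPKM, and Utf1, a chromatin-associated factor, from 312 ± 26.8 to 187 ± 10.1 FPKM. In contrast Lin28a, which binds let-7 precursors, rose from 43.4 ± 2.90 to 99.0 ± 1.25 FPKM. Sall4 stood at 38.0 ± 2.40 FPKM in WT and 37.3 ± 0.972 in R153A and Tdgf1 at 432 ± 17.6 and 429 ± 14.4. The list moved down (camera adjusted p = 0.0103). The p ranged from 0.00332 to 0.0744 over the alternatives, and the list did not pass under quantile normalization. Camera gave an adjusted p = 0.515 with an estimated correlation.

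Formative and primed pluripotency genes, which mark the epiblast around implantation, moved up. Of 20 tested, 15 rose, 3 fell and 2 did not pass, the same counts as when adjusted over the list alone. Besides Pim2, the largest rises were those of Krt18, a simple-epithelial keratin, from 18.8 ± 1.39 to 143 ± 9.11 FPKM, Sox4, an SRY-box factor, from 3.19 ± 0.247 to 22.6 ± 1.04 FPKM, and Pou3f1, which encodes OCT6, from 7.60 ± 0.513 to 39.9 ± 0.685 FPKM. The members that fell were Etv4 (29.2 ± 2.59 to 14.3 ± 0.368 FPKM), Tcf15 (70.9 ± 6.77 to 39.6 ± 3.496 FPKM) and Otx2 (48.2 ± 0.896 to 31.5 ± 0.532 FPKM), the last a homeobox factor of the formative epiblast. Etv5 stood at 78.0 ± 3.10 FPKM in WT and 75.3 ± 0.742 in R153A and Dnmt3a at 17.9 ± 1.46 and 18.7 ± 0.655. The camera test gave an adjusted p = 4.9e-04 (range 8.3e-05 to 0.0326 over the alternatives). The list had an adjusted p = 0.425 with an estimated correlation.

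**Figure D2:**
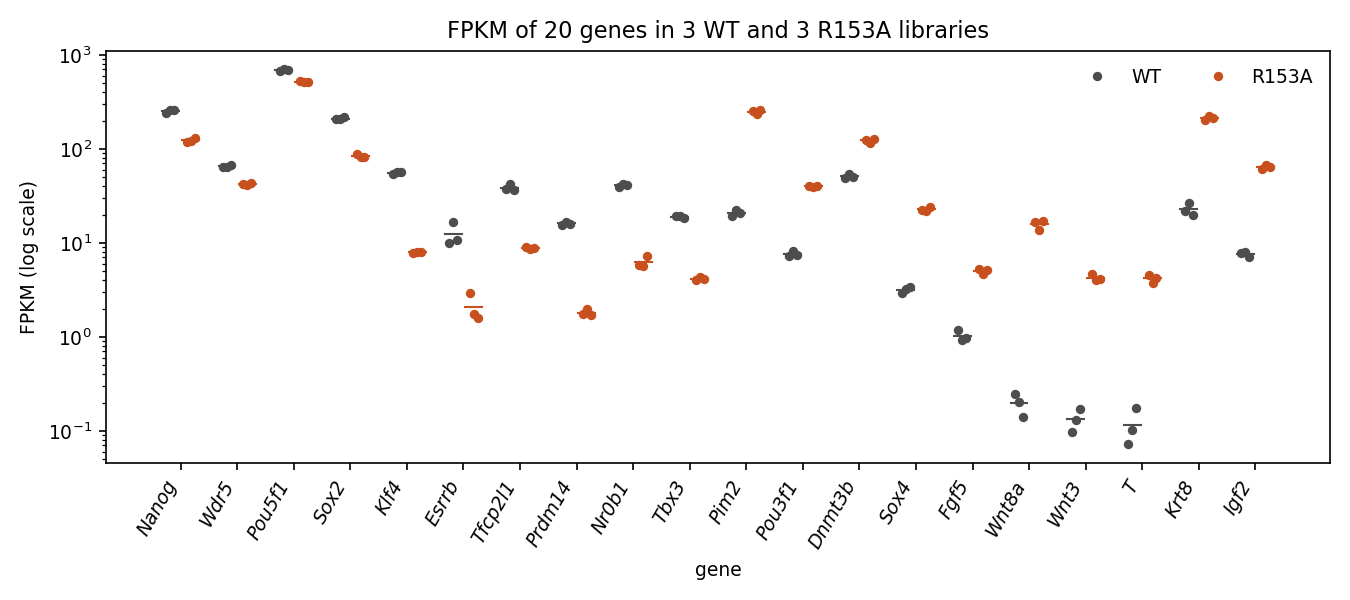
FPKM on a log axis of 20 genes in the 3 WT (gray) and 3 R153A (orange) libraries, 1 point per library, with a line at each group mean. Nanog, Wdr5, Pou5f1, Sox2, Klf4, Esrrb, Tfcp2l1, Prdm14, Nr0b1 and Tbx3 lie lower in all 3 R153A libraries, and the other 10 genes lie higher in all 3. The genes were picked for display, and Pou5f1, Tbx3, Dnmt3b and Fgf5 were not taken by the naming rule. Not shown are Otx2, Tcf15 and Etv4 of the formative list, which fell, and the core factor Lin28a, which rose.

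Among lineage genes, those of mesoderm and the primitive streak, where gastrulation begins, moved up. Of 25 in the table, 12 were tested, of which 9 rose, 2 fell and 1 did not pass, also when adjusted over the list alone. Wnt8a, Fgf8, T, Wnt3 and Cdx2 lay under 1 FPKM in every WT library. They passed the filter only through R153A, so their rise decided that they were tested. Fgf8, a growth factor of the streak, rose from 0.174 ± 0.133 to 4.98 ± 0.832 FPKM. T, which encodes brachyury, rose from 0.117 ± 0.0535 to 4.19 ± 0.373 FPKM, and Wnt3, a WNT ligand needed for streak formation, from 0.133 ± 0.0367 to 4.25 ± 0.342 FPKM. Fgf17 and Eomes fell, from 14.5 ± 1.01 to 3.92 ± 0.270 FPKM and from 3.38 ± 0.581 to 2.42 ± 0.353 FPKM, and Hand1 stood at 2.66 ± 0.308 FPKM in WT and 2.61 ± 0.305 in R153A. The Eomes call ended in 3 alternatives, such as without WT replicate 2 (limma adjusted p = 0.0737). The mesoderm list moved up (camera adjusted p = 0.00719, range 0.00281 to 0.0188 over the 16 alternatives that tested it). It had an adjusted p = 0.215 with an estimated correlation. Its mean log2 fold change was 1.26, and 0.65 with no filter on low values. Of 27 primitive endoderm genes in the table, 14 were tested. Of these 8 rose, 4 fell and 2 did not pass, with the same counts when adjusted over the list alone. Foxa2 and Fst passed the filter only through R153A. That list was not called (camera adjusted p = 0.143) except for genes of at least 5 FPKM (0.0499). Foxa2, a forkhead factor of endoderm, rose from 0.176 ± 0.0811 to 3.40 ± 0.341 FPKM. Fst, the activin antagonist follistatin, rose from 0.170 ± 0.0238 to 3.22 ± 0.293 FPKM, Cited1, a transcriptional coregulator, from 3.07 ± 0.354 to 12.6 ± 0.552 FPKM, and Lrp2, the endocytic receptor megalin, from 2.62 ± 0.419 to 10.3 ± 0.418 FPKM. The 4 that fell were Sox7, Lama1, Apoe and Lamc1. The endoderm regulator Gata4 stood at 1.48 ± 0.216 FPKM in WT and 1.48 ± 0.156 in R153A and Amn at 2.29 ± 0.278 and 2.24 ± 0.239. Of 19 trophectoderm genes in the table, 13 were tested. Of these 8 rose, 3 fell and 2 did not pass, the same as when adjusted over the list alone. No call was made for the list (camera adjusted p = 0.0622), but it was called up in 5 of 17 alternatives (range 0.0377 to 0.0917). The simple-epithelial keratins led it, with Krt8 rising from 22.7 ± 3.55 to 214 ± 8.89 FPKM, Krt19 from 9.12 ± 1.04 to 53.9 ± 1.82 FPKM and Krt7 from 1.20 ± 0.328 to 7.61 ± 0.479 FPKM. Tfap2c, Tead4 and Eomes fell, and Esx1 stood at 6.48 ± 0.820 FPKM in WT and 6.34 ± 0.253 in R153A. Of 22 neuroectoderm genes in the table, 6 were tested, of which 3 rose and 3 fell, as when adjusted over the list alone. Nes, the intermediate filament nestin, rose from 3.99 ± 0.444 to 23.3 ± 1.21 FPKM and Sox11 from 3.47 ± 0.128 to 8.21 ± 0.501 FPKM, as did Olig2. In contrast Tubb3, a neuronal tubulin, fell from 48.3 ± 4.07 to 15.3 ± 0.112 FPKM and Ncam1, an adhesion molecule, from 1.83 ± 0.171 to 0.334 ± 0.106 FPKM, as did Map2. Ncam1 lay under 1 FPKM in every R153A library and passed the filter only through WT. That list's mean log2 fold change was 0.10, its median -0.016 and its direction by camera down, with no call (camera adjusted p = 0.667). The mean was below 0 with a pseudocount of 0.1, under quantile normalization and after the GC and length correction. Of 39 Hox genes only 2 passed the expression filter, of which 1, Hoxb13, fell from 1.58 ± 0.322 to 0.412 ± 0.107 FPKM. Hoxb13 also passed when adjusted over the list alone. It lay under 1 FPKM in every R153A library and passed the filter only through WT.

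Of the genes of the two-cell-like state, a rare state with transcripts of the early cleavage embryo, 5 of 25 measured members were tested. Of these, 4 rose and 1 fell, as when adjusted over the list alone. The 4 that rose lay under 1 FPKM in every WT library and passed the filter only through R153A. Their rise thus decided that they were tested, and the count of 4 is no separate support. Zscan4f rose from 0.102 ± 0.0223 to 2.29 ± 0.286 FPKM. Gm4340 rose from 0.115 ± 0.0142 to 2.26 ± 0.174 FPKM, Zscan4c from 0.0699 ± 0.0248 to 1.61 ± 0.236 FPKM and Gm5662 from 0.144 ± 0.0840 to 1.51 ± 0.295 FPKM, while Eif1a fell from 52.4 ± 2.58 to 47.2 ± 1.91 FPKM. The Eif1a call ended in 6 alternatives, among them the replicate block (limma adjusted p = 0.0532), limma without a trend (0.0691) and no filter on low values (0.0531). Zscan4f and Zscan4c are near-identical copies, so their separate values are uncertain. As a list these genes moved up (camera adjusted p = 0.0388, 0.0601 without WT replicate 2, range 2.4e-05 to 0.0601 over the 16 alternatives that tested the list). There was an adjusted p = 0.510 with an estimated correlation. The list's mean log2 fold change was 1.08, and 0.55 with no filter on low values, where the camera adjusted p was 2.4e-05.

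Signalling lists moved in different directions. In the LIF and STAT3 pathway, 11 of 16 tested genes fell, 3 rose and 2 did not pass, the same as when adjusted over the list alone. Besides Klf4, Tfcp2l1, a target of STAT3, fell from 38.6 ± 3.15 to 8.84 ± 0.211 FPKM, and Bcl3, an IκB family member, from 25.7 ± 2.00 to 8.53 ± 0.406 FPKM. Junb, Pim1 and Jak2 rose, and Ccrn4l and Cish stood at 16.5 ± 1.32 FPKM in WT and 17.0 ± 1.06 in R153A and at 1.93 ± 0.197 and 2.12 ± 0.2996. The list moved down (camera adjusted p = 3.0e-04). That p ranged from 1.1e-04 to 0.00182 over the alternatives. There was an adjusted p = 0.339 with an estimated correlation. Of 16 WNT targets in the table, 11 were tested, of which 6 rose, 2 fell and 3 did not pass, also when adjusted over the list alone. Besides Sp5, T and Wnt3, Cdx2, a caudal-type homeobox factor, rose from 0.117 ± 0.0364 to 2.78 ± 0.392 FPKM. Sp5, T, Wnt3 and Cdx2 lay under 1 FPKM in every WT library and passed the filter only through R153A. Notum fell, as did Ccnd1, whose call ended in 7 alternatives, among them the replicate block (limma adjusted p = 0.0574), limma without a trend (0.0617) and no filter on low values (0.0792). Tcf7 stood at 19.8 ± 0.639 FPKM in WT and 19.04 ± 1.18 in R153A, Znrf3 at 2.49 ± 0.330 and 2.72 ± 0.0635 and Lef1 at 7.44 ± 0.607 and 8.07 ± 1.30. The camera adjusted p of the WNT targets was 0.0418. It was 0.0601 without WT replicate 2, 0.0618 without WT replicate 3 and 0.324 for genes of at least 5 FPKM (range 0.00616 to 0.324 over the alternatives). The same list had an adjusted p = 0.356 with an estimated correlation. Of 17 Nodal and BMP genes, 9 rose, 4 fell and 4 did not pass, as when adjusted over the list alone. The list was not called (camera adjusted p = 0.111) except for genes of at least 5 FPKM (0.0404). The BMP-induced Id3 and Id1 rose from 8.61 ± 0.836 to 66.7 ± 8.62 FPKM and from 17.1 ± 0.419 to 73.0 ± 2.73 FPKM. The Nodal target Lefty1 rose from 28.9 ± 2.66 to 125 ± 6.13 FPKM. Smad7, Bmp4, Gdf3 and Smad6 fell, and the members that did not pass were Tdgf1, Bambi (1.19 ± 0.333 and 1.25 ± 0.0809 FPKM), Acvr2b (10.9 ± 0.687 and 11.5 ± 0.281) and Id4 (1.95 ± 0.392 and 2.09 ± 0.0950). Of 17 FGF and ERK response genes, 10 rose, 2 fell and 5 did not pass, the same as when adjusted over the list alone. The list was not called (camera adjusted p = 0.139). Dusp6, a phosphatase that restrains ERK, rose from 8.97 ± 0.749 to 25.0 ± 2.04 FPKM. Spred1, an inhibitor of RAS signalling, rose from 6.59 ± 0.692 to 13.1 ± 0.4001 FPKM, and Egr1, an immediate early factor, from 0.992 ± 0.0656 to 2.68 ± 0.257 FPKM, whereas Etv4 and Ier2 fell. Etv5, Fos, Spred2, Spry2 and Spry4 did not pass, with log2 fold changes between -0.05 for Fos and 0.02 for Spry4.

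Subunits of WDR5 and COMPASS complexes went both ways. Of 18 tested, 7 rose, 7 fell and 4 did not pass, also when adjusted over the list alone, and 4 rose and 7 fell under median-ratio scaling. Besides Wdr5, Kmt2c, a histone methyltransferase, fell from 10.5 ± 1.17 to 4.15 ± 0.440 FPKM and Rbbp5, a core subunit, from 24.7 ± 1.23 to 14.7 ± 0.352 FPKM, whereas Setd1b, a histone methyltransferase, rose from 3.97 ± 0.305 to 7.06 ± 0.782 FPKM. Kmt2b stood at 18.1 ± 1.59 FPKM in WT and 17.6 ± 0.820 in R153A, Hcfc1 at 45.1 ± 5.05 and 44.9 ± 1.70, Paxip1 at 13.8 ± 0.644 and 13.9 ± 0.762 and Kmt2a at 8.55 ± 0.359 and 9.85 ± 1.07. The list's mean log2 fold change was -0.07 and its median 0.0043, with no call (camera adjusted p = 0.293). Of 14 genes of DNA methylation and its removal, 5 rose, 7 fell and 2 did not pass, the same as when adjusted over the list alone. The list was not called (camera adjusted p = 0.0676) except without a filter on low values (0.0424). Besides Prdm14, the methylcytosine dioxygenase genes Tet1 and Tet2 fell from 37.3 ± 3.90 to 13.7 ± 0.914 FPKM and from 9.74 ± 1.26 to 3.505 ± 0.0876 FPKM, and Zfp57, which protects imprints, fell from 83.2 ± 11.4 to 32.7 ± 0.1101 FPKM. The members that rose were Dnmt3b, Tdg, Gadd45b, Gadd45g and Tet3, of which Dnmt3b, a de novo DNA methyltransferase, went from 51.2 ± 2.89 to 123 ± 6.16 FPKM. Gadd45g did not pass without a filter on low values (limma adjusted p = 0.0652). Uhrf1 stood at 76.2 ± 1.84 FPKM in WT and 75.2 ± 2.43 in R153A. Of 19 Polycomb genes, 10 fell, 4 rose and 5 did not pass, as when adjusted over the list alone. Phf19, Jarid2 and Mtf2, accessory subunits of the repressive complex that contains EZH proteins, fell from 9.41 ± 0.936 to 2.89 ± 0.105 FPKM, from 86.3 ± 5.46 to 54.95 ± 1.99 FPKM and from 43.6 ± 3.15 to 28.7 ± 1.69 FPKM. The methyltransferase Ezh2 rose from 13.6 ± 0.733 to 43.7 ± 0.998 FPKM. Kdm2b, Cbx7 and Bmi1 also rose, but Bmi1 did not pass under quantile normalization (limma adjusted p = 0.245). Aebp2 (14.3 ± 1.54 and 12.9 ± 1.19 FPKM), Pcgf1 (8.58 ± 1.26 and 8.07 ± 1.32), Phc1 (92.9 ± 4.51 and 97.8 ± 1.29), Ring1 (3.53 ± 0.436 and 3.84 ± 0.335) and Cbx2 (9.34 ± 0.301 and 10.3 ± 0.935) did not pass. The Polycomb list moved down (camera adjusted p = 0.0311). Its p ranged from 0.0188 to 0.0777 over the alternatives, and the list did not pass under quantile normalization. The list had an adjusted p = 0.510 with an estimated correlation.

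Imprinted genes, which are expressed from 1 parental allele, moved up. Of 22 tested, 18 rose, 1 fell and 3 did not pass, the same as when adjusted over the list alone. Igf2, a fetal growth factor, rose from 7.62 ± 0.493 to 64.1 ± 3.00 FPKM. H19, the noncoding RNA gene next to it, rose from 3.82 ± 0.662 to 31.4 ± 1.21 FPKM. Nnat, neuronatin, rose from 15.3 ± 1.20 to 77.1 ± 2.14 FPKM, and Peg10, a retrotransposon-derived gene, from 91.3 ± 8.32 to 344 ± 12.1 FPKM. Igf2r fell from 16.8 ± 1.88 to 12.1 ± 0.442 FPKM. Mkrn3, Ndn and Peg12 stood at 4.13 ± 0.375 FPKM in WT and 3.45 ± 0.474 in R153A, at 12.4 ± 1.02 and 12.3 ± 0.576 and at 3.71 ± 0.159 and 3.73 ± 0.414. The whole list moved up (camera adjusted p = 9.9e-05, range 1.9e-05 to 2.0e-04 over the alternatives). The test gave an adjusted p = 0.215 with an estimated correlation. Germline genes moved down. Of 25 in the table, 15 were tested, of which 9 fell, 1 rose and 5 did not pass, also when adjusted over the list alone. Dazl lay under 1 FPKM in every R153A library and passed the filter only through WT. The mean log2 fold change of the germline list was -0.47, and -0.26 with no filter on low values. Stra8, a gate of meiotic entry, fell from 5.68 ± 0.937 to 1.32 ± 0.241 FPKM. Dazl, an RNA-binding protein of germ cells, fell from 2.45 ± 0.231 to 0.571 ± 0.123 FPKM, Tex11, a meiotic gene, from 2.43 ± 0.291 to 0.707 ± 0.464 FPKM, and Piwil2, a piRNA-binding protein, from 7.18 ± 0.457 to 3.51 ± 0.343 FPKM. Sycp3 rose from 10.6 ± 1.07 to 12.9 ± 0.401 FPKM, but did not pass under quantile normalization (limma adjusted p = 0.0505). Ddx4, Slc25a31, Mael, Sycp1 and Taf7l did not pass, with log2 fold changes from -0.12 for Ddx4 to 0.10 for Taf7l. The germline list had a camera adjusted p = 7.6e-04 (0.0590 for genes of at least 5 FPKM, range 2.9e-04 to 0.0590 over the alternatives). It had an adjusted p = 0.215 with an estimated correlation. Of 7 sex-linked genes tested, 3 rose, 1 fell and 3 did not pass, as when adjusted over the list alone, while quantile normalization gave 3 and 3. Rlim, an activator of X inactivation, rose from 37.0 ± 0.681 to 91.0 ± 2.56 FPKM, and Xist, the RNA that coats the inactive X, from 1.97 ± 0.118 to 5.42 ± 0.478 FPKM. Its antisense partner Tsix rose from 1.30 ± 0.140 to 3.16 ± 0.550 FPKM, but reads of that pair cannot be told apart here because no strand rule was given. Huwe1, an X-linked ubiquitin ligase, fell from 93.9 ± 11.9 to 77.6 ± 4.39 FPKM, a call that ended without R153A replicate 2 (limma adjusted p = 0.0589) and without a filter on low values (0.0708). Kdm5c and Eif2s3x stood at 31.8 ± 2.59 FPKM in WT and 28.9 ± 0.274 in R153A and at 147 ± 9.08 and 147 ± 4.71. The sex-linked list had a mean log2 fold change of 0.39 and a median of -0.0066, with no call (camera adjusted p = 0.518). The Y-linked genes Ddx3y and Eif2s3y lay at 0.0123 ± 0.0129 FPKM in WT and 0.0315 ± 0.0171 in R153A and at 0.0239 ± 0.00120 and 0.0173 ± 0.0150.

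Targets of p53, the DNA damage response factor, rose in 15 of 19 cases, with 2 that fell and 2 that did not pass. When adjusted over the list alone, 15 rose and 3 fell. Btg2, an antiproliferative factor, rose from 7.73 ± 0.419 to 33.6 ± 0.921 FPKM. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose from 20.0 ± 0.628 to 75.5 ± 0.435 FPKM, Trp53inp1, a p53-induced nuclear protein, from 25.3 ± 0.447 to 75.5 ± 2.22 FPKM, and Plk2, a polo-like kinase, from 5.91 ± 0.504 to 18.7 ± 0.477 FPKM. Gdf15 and Rrm2b fell, from 6.67 ± 0.922 to 1.95 ± 0.498 FPKM and from 2.56 ± 0.160 to 2.05 ± 0.0788 FPKM, and the call of Rrm2b ended when WT replicate 3 (limma adjusted p = 0.0879) or R153A replicate 1 (0.0835) or 2 (0.0517) was left out. Sesn1 and Bax stood at 7.04 ± 0.262 FPKM in WT and 6.26 ± 0.138 in R153A and at 169.8 ± 14.9 and 186 ± 9.50. The list moved up (camera adjusted p = 2.4e-04). The p ranged from 1.9e-05 to 5.6e-04 over the alternatives. It had an adjusted p = 0.339 with an estimated correlation. In the integrated stress and heat shock response, 13 of 18 genes fell, 1 rose and 4 did not pass. When adjusted over the list alone, 13 fell and 2 rose. Ddit3, which encodes CHOP, fell from 48.6 ± 4.44 to 17.6 ± 0.296 FPKM. Trib3, a pseudokinase, fell from 33.5 ± 2.40 to 16.9 ± 0.228 FPKM, and Asns, asparagine synthetase, from 171 ± 6.12 to 90.4 ± 3.69 FPKM, whereas Ddit4, an inhibitor of mTORC1, rose from 260.0 ± 12.7 to 568 ± 12.4 FPKM. The 4 members that did not pass were Atf3, Dnajb1, Hspa1b and Hspa1a, with log2 fold changes from 0.02 for Atf3 to 0.22 for Hspa1a. That list moved down (camera adjusted p = 2.5e-04). That p ranged from 2.3e-05 to 0.00133 over the alternatives. Camera gave an adjusted p = 0.339 with an estimated correlation. Of 28 cell cycle genes, 5 rose, 7 fell and 16 did not pass. There were 5 that rose and 5 that fell when adjusted over the list alone, and 4 and 12 under median-ratio scaling. Ccnd3, a D-type cyclin, fell from 231 ± 9.12 to 83.7 ± 1.38 FPKM and the transcription factor gene E2f1 from 20.7 ± 0.469 to 15.7 ± 1.08 FPKM. In contrast Cdkn2b, an inhibitor of CDK4 and CDK6, rose from 1.95 ± 0.447 to 3.90 ± 0.3001 FPKM and Ccne2, an E-type cyclin, from 2.88 ± 0.210 to 4.93 ± 0.299 FPKM. Foxm1, Plk1 and Bub1 were the other members that rose, a call that for Bub1 ended in 5 alternatives, such as median-ratio scaling (limma adjusted p = 0.151). No call was made for the list (camera adjusted p = 0.273).

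Of 24 glycolysis and hypoxia genes, 18 rose, 3 fell and 3 did not pass, the same as when adjusted over the list alone. Under median-ratio scaling 14 rose and 4 fell. Egln3, an oxygen-sensing prolyl hydroxylase, rose from 25.1 ± 2.38 to 59.8 ± 0.402 FPKM, as did Ddit4. Pfkp, a phosphofructokinase, fell from 151 ± 10.4 to 44.8 ± 0.698 FPKM. Vegfa, the vascular growth factor, fell from 50.7 ± 2.60 to 19.7 ± 1.11 FPKM, and Hk1, a hexokinase, from 16.5 ± 0.821 to 12.8 ± 0.843 FPKM. Hk2, Aldoa and Pdk1 stood at 72.7 ± 8.61 FPKM in WT and 67.2 ± 0.374 in R153A, at 989 ± 27.2 and 1051 ± 35.8 and at 32.3 ± 1.61 and 34.8 ± 0.378. The list moved up (camera adjusted p = 0.0135). Its p ranged from 0.00153 to 0.0320 over the alternatives. There was an adjusted p = 0.510 with an estimated correlation. Of 22 genes of cholesterol biosynthesis and uptake, 13 rose, 1 fell and 8 did not pass, as when adjusted over the list alone. Under median-ratio scaling 12 rose and 4 fell. The pathway enzymes Idi1, Lss and Sc5d rose from 27.6 ± 0.640 to 52.3 ± 2.60 FPKM, from 16.0 ± 0.863 to 26.2 ± 0.856 FPKM and from 8.04 ± 0.629 to 13.1 ± 0.451 FPKM, while Ebp fell from 19.5 ± 1.13 to 15.3 ± 1.43 FPKM. Tested together, the members moved up (camera adjusted p = 0.0363, 0.0501 after the GC and length correction, range 0.00850 to 0.0501 over the alternatives). The same test gave an adjusted p = 0.510 with an estimated correlation. Of 47 cytosolic ribosomal protein genes, 8 fell, 1 rose and 38 did not pass, and 0 rose and 0 fell when adjusted over the list alone. Median-ratio scaling gave 18 that fell and 0 that rose, and quantile normalization 7 and 3. Rps23 and Rps4x fell from 1066 ± 89.1 to 896 ± 24.7 FPKM and from 1602 ± 72.0 to 1394 ± 15.5 FPKM. Rps18 and Rpl4 fell from 1643 ± 122 to 1439 ± 24.0 FPKM and from 1477 ± 17.5 to 1298 ± 26.2 FPKM, and Rps19 rose from 911 ± 96.5 to 1030.5 ± 19.2 FPKM, a call that ended in 8 alternatives. Under quantile normalization Rps18 and Rpl4 no longer passed (limma adjusted p = 0.102 and 0.124). Rps18 did not pass without any one of the R153A replicates (0.0742, 0.0512 and 0.0735) or without a filter on low values (0.0961). The ribosomal list had a camera adjusted p = 0.0103 (0.104 without WT replicate 3, 0.354 under quantile normalization, range 1.6e-04 to 0.354 over the alternatives). It had an adjusted p = 0.686 with an estimated correlation.

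Interferon response genes moved up, led by genes of class I antigen presentation. Of 17 tested, 10 rose, 4 fell and 3 did not pass, the same as when adjusted over the list alone. Psmb8, an immunoproteasome subunit, rose from 1.46 ± 0.38004 to 14.4 ± 0.625 FPKM. Tap1, a peptide transporter, rose from 1.45 ± 0.0801 to 9.07 ± 0.125 FPKM, and the class I heavy chain genes H2-K1 and H2-D1 from 10.3 ± 0.497 to 51.3 ± 2.77 FPKM and from 3.23 ± 0.223 to 23.3 ± 1.20 FPKM. Reads shared among H2 genes leave their separate values uncertain. The antiviral genes Oas1a, Ifitm2 and Ifitm3 and the signal transducer Stat2 fell. Irf9 and Ddx58 stood at 2.06 ± 0.176 FPKM in WT and 1.93 ± 0.224 in R153A and at 5.31 ± 0.657 and 5.23 ± 0.436. As a group the members moved up (camera adjusted p = 0.0398, 0.0601 without WT replicate 2, range 0.0139 to 0.0601 over the alternatives). Its test had an adjusted p = 0.339 with an estimated correlation. Genes of extracellular matrix and adhesion rose in 17 of 21 cases and fell in 4, as when adjusted over the list alone. Cldn6, a tight-junction claudin, rose from 25.4 ± 1.14 to 101 ± 0.758 FPKM. Itgb5, an integrin, rose from 8.01 ± 0.228 to 23.5 ± 0.234 FPKM, and Lama5, a laminin chain, from 20.1 ± 1.61 to 55.7 ± 3.80 FPKM. Spp1, the secreted phosphoprotein osteopontin, fell from 328 ± 6.18 to 123 ± 4.41 FPKM, as did Timp1, Fn1 and Itga6. This list moved up (camera adjusted p = 0.00828, range 0.00137 to 0.0239 over the alternatives). Camera gave an adjusted p = 0.389 with an estimated correlation. Of 23 fibroblast and feeder markers in the table, listed to look for other cells in the cultures, 11 were tested. Of these 7 rose, 1 fell and 3 did not pass, also when adjusted over the list alone. Under quantile normalization 6 rose and 2 fell. Col1a2 lay under 1 FPKM in every WT library and passed the filter only through R153A. The mean log2 fold change of this list was 0.71, and 0.50 with no filter on low values. Tagln, an actin-binding protein of contractile cells, rose from 6.20 ± 1.19 to 44.3 ± 0.402 FPKM. Mmp2, a matrix protease, rose from 1.23 ± 0.125 to 6.48 ± 0.240 FPKM, and the collagen genes Col5a1 and Col1a1 from 1.35 ± 0.148 to 4.696 ± 0.441 FPKM and from 1.17 ± 0.258 to 2.82 ± 0.102 FPKM. Vim fell from 26.8 ± 1.61 to 19.9 ± 0.904 FPKM. Thy1, Loxl1 and S100a4 stood at 3.79 ± 0.467 FPKM in WT and 3.19 ± 0.274 in R153A, at 1.40 ± 0.199 and 1.58 ± 0.181 and at 1.67 ± 0.772 and 2.05 ± 0.0373. No call was made for that list (camera adjusted p = 0.0557), but it was called up in 9 of the 16 alternatives that tested it (range 9.0e-04 to 0.1102).

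**Figure D3:**
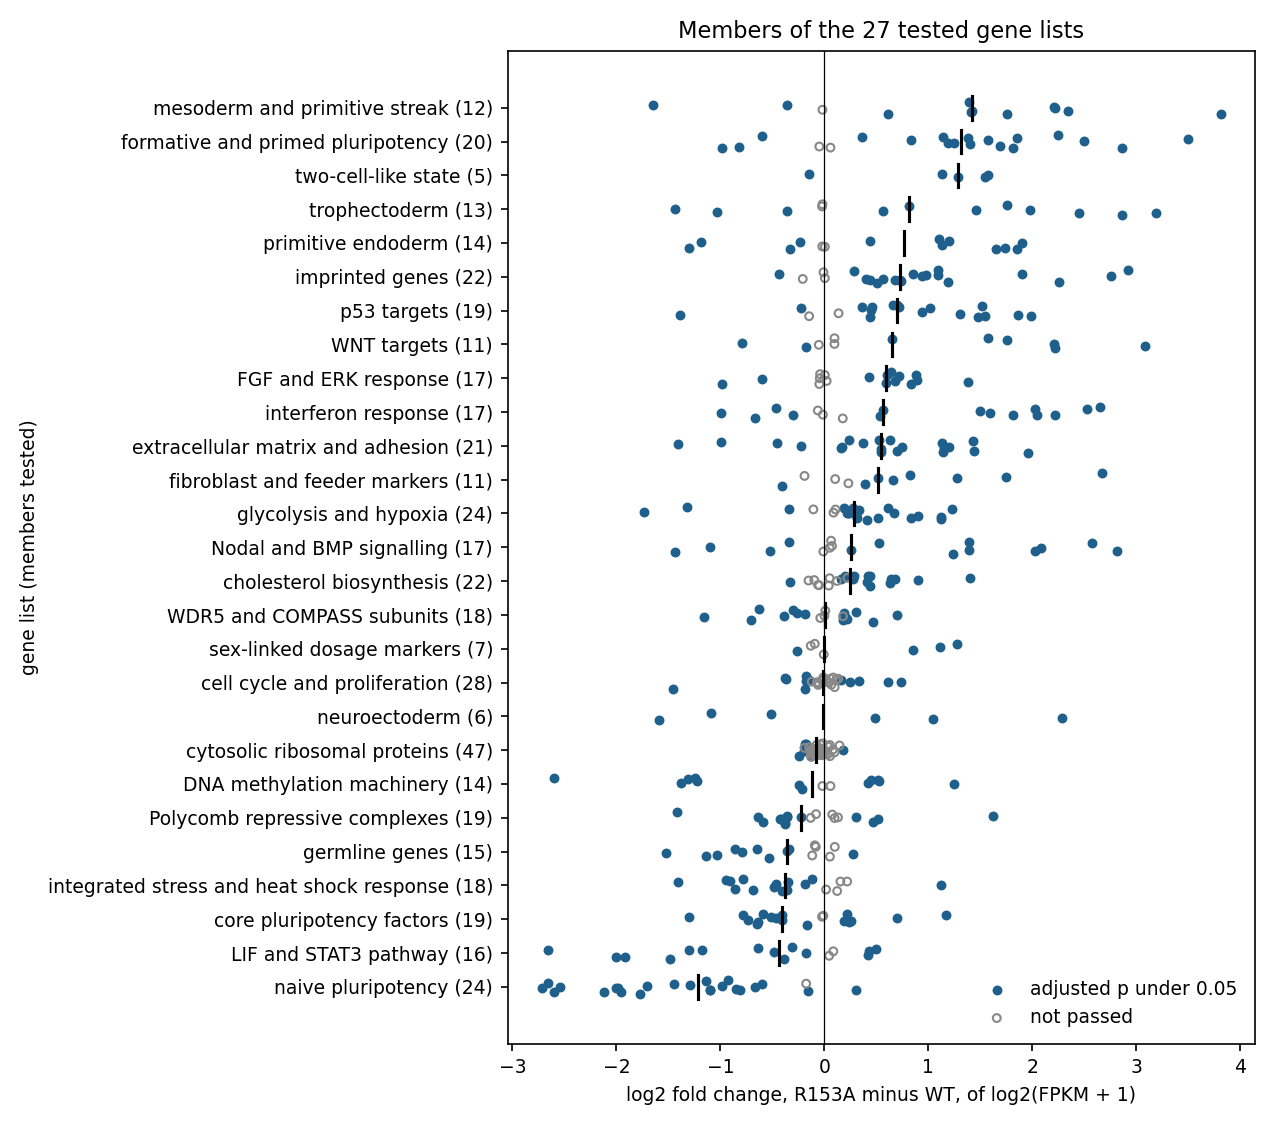
Log2 fold change (R153A minus WT) on the x axis of the tested members of 27 gene lists on the y axis, with the number tested in parentheses. Filled points passed a limma adjusted p of 0.05 and open points did not. The bar marks each list's median, and the medians run from -1.22 for naive pluripotency to 1.42 for mesoderm and primitive streak.

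In total 17 of the 27 lists were called by camera with a preset correlation of 0.01, 10 up and 7 down. With an estimated correlation camera called 0 lists, with 4 at an unadjusted p under 0.05 (naive pluripotency, mesoderm and primitive streak, germline genes and imprinted genes). For mesoderm and germline genes that correlation was -0.0032 and 0.0040, below the preset 0.01. Their unadjusted camera p still rose, from 0.0021 to 0.032 and from 2.0e-04 to 0.018. Higher correlation within these lists was therefore not what raised their p, and the cause was not tested. Fry, which tests a list's own direction without comparing it with other genes, called 23. At the preset correlation camera also called 2 to 10 lists in every other split of the libraries into 3 and 3, where 0 genes were called. Those splits keep part of the difference between WT and R153A. The number of false list calls therefore cannot be read from them. The labels do not say whether the 3 libraries of a group came from separate cultures or clones. The p-values therefore measure only the spread among these libraries, which may be technical. For the same reason the genotype could not be separated from other differences between the cell lines.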

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

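The GC and length correction was chosen after the data were seen, and all other alternatives before. The number of genes changed stayed within 1.5 times of 7062 in every alternative run, from 4860 with a filter of 5 FPKM to 8265 with no filter, and among the genes called higher it fell to 2901 with the filter of 5 FPKM, where fewer genes were tested. Changes of at least 2-fold numbered 1561 (1122 higher and 439 lower) with a pseudocount of 0.1, which shrinks low values less, and 608 (407 higher) with the filter of 5 FPKM. Leaving out 1 library gave 6282 to 6909 calls and 978 to 996 of at least 2-fold. Of the genes taken by the naming rule none changed direction, and Rps18, Rpl4 and Huwe1 lost their call in some alternatives. Of the other called list members named in the report, Bmi1, Bub1, Ccnd1, Eif1a, Eomes, Gadd45g, Rex2, Rps19, Rrm2b and Sycp3 lost it in 1 to 8 of them, and none changed direction. Many of the members that did not pass gained a call or changed direction in some. Camera with an estimated correlation called 0 lists in all, 0 higher and 0 lower, with 4 of 27 at an unadjusted p under 0.05, while fry called 23, of which 16 higher. Quantile normalization left 4 lists lower, without core pluripotency, Polycomb and ribosomal proteins. The call was also lost for WNT targets (FPKM of 5, without WT replicate 2 or 3), germline genes (FPKM of 5), two-cell-like state and interferon response (without WT replicate 2), ribosomal proteins (without WT replicate 3) and cholesterol biosynthesis (GC and length correction). Calls were gained for fibroblast and feeder markers in 9 of 16 alternatives, trophectoderm in 5 of 17, primitive endoderm and Nodal and BMP signalling with the filter of 5 FPKM and DNA methylation without a filter. The causes were not tested. Set against the other genes, the neuroectoderm list was never called and lay at -0.014. It lay between -0.035 and 0.0012 when 1 library was left out, the highest without WT replicate 2, but at -0.22 with a pseudocount of 0.1, -0.12 under TPM and -0.086 with a pseudocount of 0.5, and its own mean, which fry tests, was 0.10, but -0.054 with a pseudocount of 0.1, -0.034 under quantile normalization and -0.024 after the GC and length correction. The mean of the cell cycle list also crossed 0, without WT replicate 2 (0.0033). The cause was not tested. The correlations of the deviations of same-numbered libraries were -0.0487, -0.00946 and 0.0600, and these deviations correlated best between same numbers in 1 of the 3 cases. They gave no sign that the replicate numbers pair the libraries, but 3 libraries per group are too few to exclude it. A fit with the replicate block gave 6876 calls and raised the lists called from 17 to 19, adding trophectoderm and fibroblast and feeder markers. Depth is unknown, so no limit from counting can be given for genes listed at or near 0.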

Other observations

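Gene families formed from shared symbol stems were examined after the data were seen, and the GC and length correction and the tests on chromosomes, on scaling of changes of at least 2-fold, on other cell types and on H19 and Igf2 were also chosen after the results were seen. The 9 tested members of the Xlr family, X-linked genes expressed in lymphocytes and germ cells, all fell, from 10.7 ± 0.824 to 2.61 ± 0.446 FPKM for Xlr4b and from 19.6 ± 0.723 to 5.54 ± 0.617 FPKM for Xlr5b, with a mean log2 fold change of -1.18. Annexins, which bind membrane phospholipids in the presence of calcium, rose in 8 of 9 cases, with Anxa3 going from 1.98 ± 0.221 to 21.6 ± 0.853 FPKM, Anxa5 from 2.80 ± 0.0612 to 14.3 ± 1.71 FPKM and Anxa2 from 23.3 ± 1.70 to 64.7 ± 0.451 FPKM, while Anxa6 stood at 30.8 ± 1.77 FPKM in WT and 31.9 ± 0.741 in R153A. Claudins, the strand proteins of tight junctions, rose in 7 of 7 tested cases. Cldn4 rose from 40.8 ± 4.68 to 90.4 ± 3.81 FPKM and Cldn7 from 24.3 ± 1.13 to 41.4 ± 1.18 FPKM, beside Cldn6 in the report. Cldn9 (0.772 ± 0.221 to 2.29 ± 0.296 FPKM) and Anxa8 (0.977 ± 0.234 to 1.93 ± 0.260 FPKM) had WT means under 1 FPKM. Their rise may have decided that they were tested. The gamma-protocadherins rose in 12 of 12 tested Pcdhga genes and 7 of 7 tested Pcdhgb genes, at nearly one level (4.33 ± 0.296 to 8.52 ± 0.106 FPKM for Pcdhga1 and 4.23 ± 0.283 to 8.44 ± 0.128 FPKM for Pcdhgb1), and since these genes share their constant exons they do not count as separate observations.

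Of 21 tested genes with H2 symbols, which name the major histocompatibility region and not 1 class of genes, 15 rose and 4 fell. H2-L rose from 3.73 ± 0.192 to 27.2 ± 1.20 FPKM, H2-Q4 from 5.41 ± 0.555 to 25.4 ± 1.36 FPKM and H2-T22 from 1.42 ± 0.125 to 8.78 ± 0.388 FPKM, and H2-M5, H2-Bl, H2-Eb1 and H2-Ke6 fell, H2-M5 from 13.3 ± 0.836 to 2.70 ± 0.430 FPKM, while H2-DMa and H2-T24 stood at 1.01 ± 0.0433 FPKM in WT and 1.14 ± 0.0719 in R153A and at 1.09 ± 0.0971 and 1.34 ± 0.156. These counts of members rising and falling were identical under median-ratio scaling, TPM and quantile normalization for all of these families. Camera called these 6 families among 370, with adjusted p from 2.6e-05 for Xlr to 0.0473 for H2, but with an estimated correlation it called 0, with 3 at an unadjusted p under 0.05, and other splits of the libraries gave up to 8 families, so the family tests add little to the counts.

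The number of genes changed was weighed first. Of the 10 splits of the 6 libraries, 1, the real one, gave as many calls as 7062, and the other splits gave at most 0, with 30 to 178 genes at an unadjusted limma p under 0.05. For calls of at least 2-fold the real split gave 980 and the highest other 0 (1 of 10 splits as large). For lists called by camera at the preset correlation it gave 17, and the others gave 2 to 10 (1 of 10 as large). However, 10 splits are too few for a share under 0.05. Each other split also mixed WT and R153A libraries in both groups. Their difference then adds to the spread, so few gene calls were bound to follow, and the 0 calls are no evidence about chance. Lists were still called in every such split, so a list call at the preset correlation adds little to the counts of members. A trend with GC content or length as the whole cause is argued against by the calls after its removal. These numbered 7595, of which 6394 were among the 7062. A copy number change of a whole chromosome is argued against by chromosome medians that lay at most 0.0779 from the median of all genes on the log2 scale. Scaling could account for the excess of higher calls among all genes, which fell to 50.7% higher under median-ratio scaling, but that scaling centres the genes and so cannot decide, while among calls of at least 2-fold the higher share went from 72.1% to 66.0% under it and to 55.8% under quantile normalization, so how much of that excess comes from scaling stays open. What stays open is the difference that the labels name, R153A against wild-type Nanog, together with any other difference between the cell lines, since the design cannot separate them.

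The second pattern is the rise of antigen presentation genes (H2-K1, H2-D1, Tap1, Psmb8 and Psmb9) in R153A. Feeder fibroblasts stay open, with values on both sides. Col1a1, Col1a2 and Col3a1 together rose by only 2.89 FPKM where H2-K1 rose by 41.1 FPKM, and Vim fell. Dcn, Postn and Lum rose by only 0.198, 0.0451 and 0.0364 FPKM, and the labels give gelatin-coated dishes. On the other side Tagln rose by 38.1 FPKM, and 7 of 11 tested members of the fibroblast list rose. Blood cells rich in Ptprc, Cd74 and Lyz2 are argued against, since these together rose by 2.10 FPKM. Also open is a change within the stem cells themselves, in which class I genes may be set differently in R153A cells, but interferon genes did not all follow, with Oas1a and Stat2 lower and Irf9 at 2.06 ± 0.176 FPKM in WT and 1.93 ± 0.224 in R153A.

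The third pattern is the joint rise of H19 and Igf2, neighbours on chromosome 7 whose imprinting control region normally allows H19 on one parental allele and Igf2 on the other. A methylation change at that region alone would move them apart, and both rose, with log2 ratios of mean FPKM of 3.04 for H19 and 3.07 for Igf2. Mir675, which lies within H19, went from 3.48 ± 2.52 to 29.5 ± 0.844 FPKM and shares its reads. A shared regulator of the locus or a different mix of cell states may be the source, and neither was tested.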
